A study of Schizosaccharomyces pombe with 10 samples.

How the data were processed

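The series measured messenger and other RNA of the fission yeast Schizosaccharomyces pombe by RNA sequencing. Total RNA was extracted with hot phenol from cells grown at 29 °C in EMM2, a defined minimal medium, per the labels' protocols. The labels put 5 samples in a control group that carried a vector and 5 in a group that overexpressed bag101. The series design text calls the samples of each group independent repeats. The promoter, the plasmid marker, the time of induction, the culture density at harvest and the library kit are not given in the sources used here.

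The authors deposited 1 table of read counts per gene for each sample, with no normalization. Per the submitters' processing notes, the tools were Trimmomatic 0.32 for read trimming, STAR 2.3.0e for alignment and HTSeq, with no version, for counting, on genome build ASM294v2. The annotation release and whether counting used strand are not given in the sources used here. The counts as deposited are whole numbers, and each table ends with 5 rows that name no gene. Of these, the rows for low alignment quality and for unaligned reads hold 0 in every library. Reads that overlapped more than 1 gene (the ambiguous row) made up 10.9% to 13.1% of the listed reads in the controls and 13.7% to 16.3% in the overexpression libraries. Reads in no gene made up 0.211% to 0.276% and 0.319% to 0.502%, and reads aligned to more than 1 place 23.2% to 36.8% and 22.3% to 37.9%. All of these were left out of library sizes and tests. Counts of genes that overlap another gene or have a near-identical copy may therefore cover only part of their reads and are uncertain. Overlaps were taken on either strand here, and an overlap on the opposite strand loses reads only if counting ignored strand.

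The tables list 7017 features, of which 6843 were matched by systematic identifier to the annotation of assembly ASM294v3. This is not the authors' build, so it was used for gene names, feature classes, overlaps and neighbours only, and no coordinates are given. A total of 174 identifiers had no match. Features at 0 in all 10 libraries numbered 1352, among them 532 of the 5104 protein-coding genes. Gene reads per library ranged from 5.54 M to 11.8 M in the controls and from 10.2 M to 10.9 M in the overexpression group. A count of 0 allows up to 3 reads, which is 0.224 to 0.483 TMM-scaled CPM in these libraries. Intervals and such limits cover counting error only.

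Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM factors, and the quasi-likelihood F-test (robust) compared the 5 overexpression samples with the 5 controls without covariates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 4681 genes tested. The common biological coefficient of variation was 0.0869. Levels are CPM, counts scaled by TMM-adjusted library size, given as mean ± SD over 5 libraries, and folds are ratios of these means. Standard errors of log2 fold changes were computed from the fold change and its F statistic. Adjusted p-values of genes are from edgeR's quasi-likelihood test unless another tool is named. They measure the spread between these samples, which the series design text calls independent repeats.

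The 35 gene lists were fixed before the data were examined and matched by gene name or unique synonym. Each was tested with camera (limma 3.58.1) on edgeR log2-CPM with a preset correlation between genes of 0.01, adjusted over the 35 lists, with an estimated correlation and with fry beside it. The totals count all 35 lists, and 1 of the called lists is not reported here by name. Several lists were built from name patterns and hold members that do something else: pus1 (a pseudouridine synthase) in the proteasome list, trp1322 (a TRP-type channel) in the amino acid list, and dip1 (an actin regulator) and rlp1 (a RecA-family protein) in the ribosome biogenesis list. The list of RNA polymerase I and III subunits also takes in rrn genes, such as rrn6, which encodes an initiation factor. Lists also share members: hsp9, hsp16 and hsp104 (stress and chaperones), ctt1 and srx1 (stress and Pap1), zym1 (stress, copper and zinc), hxk1 (stress and glycolysis), leu1 (amino acids and markers), gdh1 and gdh2 (amino acids and nitrogen), rad21 (MBF and DNA repair), rhp6 and rhp23 (ubiquitin and DNA repair). The share of gene reads in each feature class was compared with an exact two-sided permutation test, whose smallest p for 5 against 5 samples is 0.00794.

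The genes named in the text follow a rule fixed before the data were examined. It took bag101, and the 12 largest rises and 12 largest falls among named protein-coding genes with a mean of at least 5 CPM, an adjusted p below 0.05 and no overlap between the groups. It added the 3 largest of each direction among genes with a systematic identifier only, up to 4 called members with the smallest p of each list, and hsf1, ssa1, ssa2, hsp104, hsp90, hsp16, bag102, ubi4, nmt1, ura4 and leu1. The rule gave 161 tested genes. Apart from members named above to describe the lists, genes outside the rule are said to be so where they are named. The design assumed that bag101 could be tested. It was listed at 0 in every library, so no test of it was made.

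The test was tried on simulated counts over 4649 genes. Of these, 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, and the rest were unchanged. It recovered 86.6% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls. Most genes were unchanged in the simulation but called in the real counts, so it does not check the scaling when most genes change. Alternatives were RLE, upper-quartile and library-total scaling, other low-count filters, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, bag101 left out, and protein-coding genes only. The following were added after the data were seen: leaving out control 2 and overexpression 1 together, using only genes that overlap no other counted gene, a test against a 1.5-fold change, and leaving out the 50 most abundant genes with libraries scaled to their remaining totals in place of TMM. No libraries were duplicates of each other: the chi-square per degree of freedom between libraries of a group ranged from 3.63 to 20.35, and from 52.96 to 101.8 for pairs with overexpression 1. Class shares, intervals and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.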

Results

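Gene expression was measured by RNA sequencing in 10 cultures of fission yeast, 5 with a vector and 5 that overexpressed bag101, which encodes a BAG-domain co-chaperone of Hsp70. The comparison asks which transcripts change when this co-chaperone is made in excess. The controls held 11.3, 5.54, 11.8, 11.8 and 11.4 M gene reads, in the order of their replicate numbers, and the overexpression libraries 10.9, 10.8, 10.2, 10.6 and 10.6 M. Log2-CPM values correlated across genes, which are not independent replicates, at 0.995 to 0.997 between controls, 0.986 to 0.995 between overexpression libraries and 0.828 to 0.846 between the groups.

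The overexpressed gene could not be read from these counts. Bag101 (SPBC16G5.11c) was listed at 0 reads in each of the 10 libraries, so the labels could not be checked by its level and every direction given here rests on them. In the annotation of ASM294v3 the gene is wholly covered by other counted genes, among them rrp42 on the opposite strand, a gene named here outside the naming rule. The thiamine-regulated gene nmt1 (SPCC1223.02) was also wholly covered and at 0 throughout. Of 699 wholly covered features, 627 were at 0 in all libraries, against 197 of 2759 features that overlap no other counted gene. The related gene bag102 did not pass the test, with a log2 fold change of 0.06 ± 0.06 (SE, adjusted p = 0.354, edgeR) and 82.5 ± 2.71 CPM in controls against 85.9 ± 7.13 in overexpression libraries (SD, n = 5 each). Its estimate changed sign, to -0.30, and was called lower when libraries were scaled by their totals.

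Most of the tested genes differed between the groups. Lsd90 rose from 72.2 ± 7.97 to 24687 ± 2448 CPM (SD, n = 5 each), a log2 fold change of 8.42 ± 0.15 (SE). The metallothionein gene zym1 rose 312.0-fold, the α-glucosidase gene agl1 250.4-fold and the small heat shock protein gene hsp16 215.5-fold. Pho1, which encodes an acid phosphatase, fell from 3793 ± 203 to 92.2 ± 32.9 CPM, and sam1, for S-adenosylmethionine synthetase, from 4127 ± 204 to 178 ± 12.5 CPM. In edgeR's quasi-likelihood test, 3912 of 4681 genes (83.6%) were called at an adjusted p below 0.05, 1892 higher and 2020 lower, of which 872 and 730 differed by more than 2-fold. The groups did not overlap in 3491 genes (74.6%), where chance gives 0.794%. Scaling set the balance of directions: 48.4% of called genes were higher with TMM factors, 50.2% with RLE, 40.2% with upper-quartile factors and 33.0% with library totals. Of genes that differed by more than 2-fold, 900 were higher and 690 lower with RLE, 713 and 988 with upper-quartile factors, and 598 and 1217 with library totals, so the larger side turned with the scaling. The median log2 fold change of all tested genes was -0.03 with TMM, -0.22 with upper-quartile factors and -0.39 with library totals, and changes are given relative to the TMM scale.

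**Figure D1:**
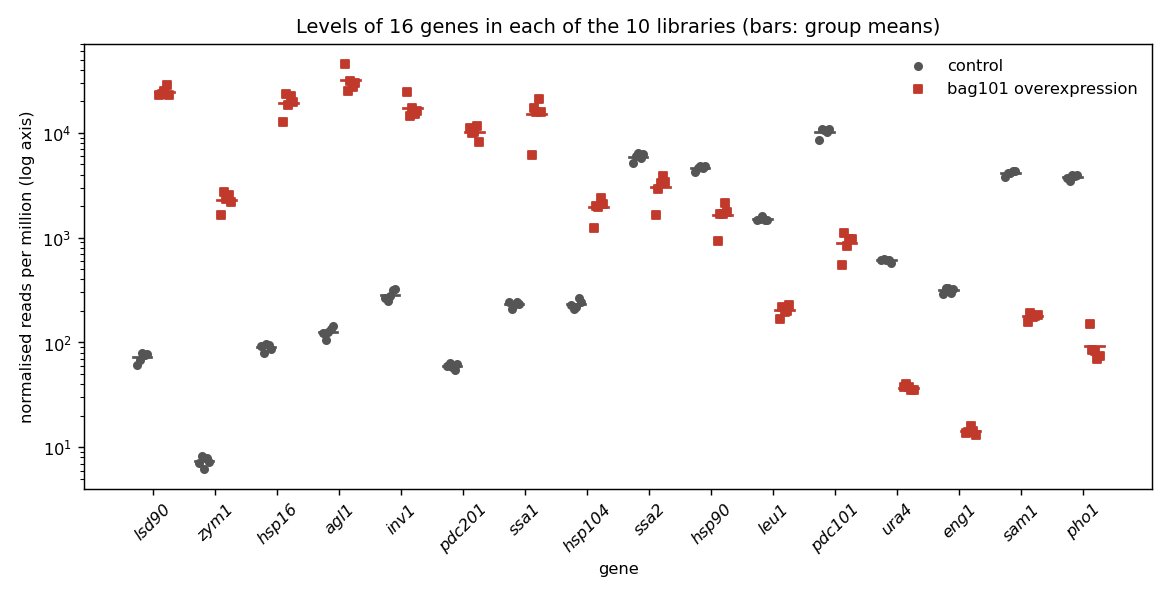
Normalised CPM (log axis) of 16 named genes (horizontal axis) in each of the 5 control libraries (grey circles) and 5 bag101 overexpression libraries (red squares), with horizontal bars at the group means. The overexpression libraries lie wholly above the controls from lsd90 to hsp104 and wholly below them from ssa2 to pho1.

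The other genes with the largest rises included a pair of hexose transporter genes and a pyruvate decarboxylase gene. Hry1 had the largest log2 fold change, 10.42 ± 0.44 (SE), with 7 reads in all controls together against 8375 in the overexpression libraries. Prl65 rose by 9.07 ± 0.13, ght7 by 7.59 ± 0.17, ght3 by 7.57 ± 0.18, mug147 by 7.46 ± 0.26, pdc201 by 7.42 ± 0.14, smp4 by 6.45 ± 0.16 and rds1 by 6.21 ± 0.19 on the log2 scale. Among genes known only by identifier, SPBPB21E7.11 rose by 8.53, SPAC186.04c by 8.33 and SPAC3G6.07 by 8.14. Among the largest falls on the log2 scale, adg1 fell by 5.04 ± 0.10 (SE), the endoglucanase gene eng1 fell by 4.46 ± 0.07, the glucanase gene exg1 fell by 4.32 ± 0.08, and the alcohol dehydrogenase gene adh4 fell by 4.01 ± 0.14. The homocysteine synthase gene met17 fell by 3.97 ± 0.13, the nitric oxide dioxygenase gene yhb1 fell by 3.80 ± 0.12, tos4 fell by 3.62 ± 0.25 and the pyruvate decarboxylase gene pdc101 fell by 3.52 ± 0.17. Among unnamed genes, SPBPB10D8.01 fell by 5.70, SPBC19G7.04 fell by 5.31 and SPAC1039.02 fell by 4.89. The highest adjusted p among all of these was 2.35e-07 for tos4 (edgeR). Of the 161 named genes, 59 overlap another counted gene, and their values are uncertain to that extent. For 10 of them the overlap covers more than 50% of their length, including mug147, rds1, eno102, fus1, rad55, rad3 and abc3.

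Genes of the core stress response rose almost together. Of 21 tested members, 19 rose and 1 fell, with a median log2 fold change of 3.58. Besides lsd90, the catalase gene ctt1 rose 21.4-fold to 4185 ± 232 CPM (SD, n = 5), the glutathione peroxidase gene gpx1 26.3-fold to 6221 ± 310 CPM and ish1 43.3-fold to 7108 ± 361 CPM. Camera gave an adjusted p of 4.06e-07 for the list, and adjusted p = 0.269 with an estimated correlation. The list of Pap1-type oxidative stress and drug resistance genes was split, with 9 of 19 higher and 6 lower (camera adjusted p = 0.433). It shares ctt1 and srx1 with the stress list. Among its other members gst3 rose 12.8-fold, the mitochondrial superoxide dismutase gene sod2 4.90-fold and hmt1 4.32-fold, while bfr1 fell 2.86-fold and the thioredoxin reductase gene trr1 2.73-fold (srx1, bfr1 and trr1 are outside the naming rule).

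Cytosolic chaperone genes went both ways. The stress-inducible Hsp70 gene ssa1 rose 65.9-fold, from 232 ± 15.01 to 15282.5 ± 5529 CPM (SD, n = 5 each), the disaggregase gene hsp104 8.32-fold and hsp9 65.6-fold, and hsf1, which encodes the heat shock transcription factor, rose 2.48-fold. The Hsp70 gene ssa2 fell by 0.96 ± 0.18 on the log2 scale, from 5909 to 3046 CPM, hsp90 fell by 1.49 ± 0.16 and the ribosome-associated J-protein gene zuo1 fell by 1.38 ± 0.07 (SE). The highest adjusted p among these genes was 1.46e-04, for ssa2 (edgeR). In overexpression replicate 1, ssa1 reached 6212 CPM, against 15816 to 21256 in the other overexpression libraries. In the whole list, which shares hsp9, hsp16 and hsp104 with the stress list, 7 of 20 tested genes were higher and 8 lower. The median was -0.00 and the mean 1.09, of opposite sign, and camera, which found the list higher, gave an adjusted p of 0.771. Of the mitochondrial chaperones and proteases, 2 of 6 were higher and 3 lower (camera adjusted p = 0.883), with hsp78 4.49-fold higher and mge1 1.99-fold lower. Their median was -0.21, their mean 0.16 and camera's direction lower. Endoplasmic reticulum folding genes had 6 of 19 higher, such as hrd1 (3.26-fold), and 12 lower, such as scj1 (2.81-fold), with a camera adjusted p of 0.522. Of the CCT chaperonin and prefoldin genes, 1 of 6 was higher and 4 lower (camera adjusted p = 0.433), and cct7 and cct3 fell by 0.39 and 0.46 on the log2 scale.

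Genes that glucose represses rose, and respiratory genes rose with them. Of 14 glucose-repressed genes tested, 11 rose and 2 fell, with a median log2 fold change of 1.38. The invertase gene inv1 rose from 287 ± 31.4 to 17415 ± 4063 CPM (SD, n = 5 each), agl1 from 126.2 ± 14.7 to 31606 ± 7929.6 CPM and the glycerol dehydrogenase gene gld1 16.7-fold. Overexpression replicate 1 was the highest for agl1 (45182 CPM, others 24979 to 30979) and inv1 (24443 CPM, others 14396 to 17149). Camera gave an adjusted p of 0.00488, adjusted p = 0.318 with an estimated correlation and 0.0711 with overlap-free genes only. The median of the overlap-free members was 3.06, so that call was lost without a smaller median. Nuclear genes for oxidative phosphorylation had 35 of 42 higher and 5 lower, a median of 1.08 and a camera adjusted p of 2.83e-06 (adjusted p = 0.289 with an estimated correlation). Among them atp5 rose 3.58-fold, cox7 3.16-fold, cox13 2.81-fold and atp16 2.42-fold. In the glycolysis and fermentation list 4 of 16 genes were higher and 10 lower, among them the pyruvate kinase gene pyk1, which fell from 5597 ± 293 to 985 ± 115 CPM (camera adjusted p = 0.174). The enolase gene eno102 had 3 reads in all controls against 411 in the overexpression libraries, a ratio of 171 (95% exact interval 58.2 to 834, counting error only), and 79.2% of its length overlaps another gene. Mitochondrial ribosomal protein genes were 19 of 35 higher and 7 lower, with mrpl7 2.60-fold and mrpl1 1.89-fold higher and mrpl24, outside the naming rule, 1.80-fold lower (camera adjusted p = 0.210).

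The genes for making ribosomes fell. Of 104 cytosolic ribosomal protein genes tested, 103 fell and none rose, with a median log2 fold change of -1.29 and a camera adjusted p of 1.36e-14. With an estimated correlation the adjusted p = 0.575. Rps403 fell from 926 ± 33.9 to 208 ± 14.5 CPM (SD, n = 5 each), and rps1402, rpl3002 and rps1502 fell by 2.29, 2.28 and 1.79 on the log2 scale. A further 22 ribosomal protein genes were at 0 in every library. Ribosome biogenesis genes had 69 of 86 lower and 8 higher, a median of -0.69 and a camera adjusted p of 2.12e-06 (adjusted p = 0.575 with an estimated correlation). The helicase gene dbp3 fell by 2.51 ± 0.11, erb1 fell by 1.54 ± 0.06 and utp22 fell by 1.28 ± 0.06 (SE). The list of RNA polymerase I and III subunits had 14 of 20 lower and 3 higher, or 15 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0638). Ker1 was 2.58-fold and rpc10 2.297-fold lower. Rrn6, which encodes an initiation factor of polymerase I rather than a subunit, was 1.57-fold higher. Translation factors were 21 of 35 lower and 7 higher, or 20 and 7 adjusted over the list alone (camera adjusted p = 0.0810), with tif52 2.19-fold and tif225 2.02-fold lower and eft201, outside the naming rule, 1.68-fold higher. For the other lists, the counts adjusted over the list alone were equal to those over all genes.

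Cell cycle genes of the G1/S transition fell. In the MBF list, named for the transcription factor of the G1/S wave, 11 of 15 genes were lower and 1 higher, with a median of -1.21 (camera adjusted p = 0.0176, adjusted p = 0.602 with an estimated correlation and 0.255 with overlap-free genes only). The kinase gene mik1 fell by 3.08 ± 0.09, the DNA polymerase α gene pol1 fell by 2.54 ± 0.10, the ribonucleotide reductase gene cdc22 fell by 1.91 ± 0.06 and the replication licensing gene cdt1 fell by 1.80 ± 0.12 on the log2 scale (SE). Cell wall glucan genes had 8 of 19 higher and 11 lower (camera adjusted p = 0.468), and gas1, exg1, ags1 and gas4 were among those that fell, gas1 from 763 ± 30.9 to 87.3 ± 15.1 CPM, while gas2 and bgl2, outside the naming rule, rose 2.87-fold and 2.09-fold. Kinetochore genes were 20 of 32 lower and 8 higher (camera adjusted p = 0.174), with spc19 2.68-fold and mis15 2.65-fold lower and fta6 2.58-fold higher. Core histone genes had 6 of 8 higher and 2 lower (camera adjusted p = 0.269), with hht3 2.55-fold higher and the H2A variant gene pht1 1.66-fold lower.

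**Figure D2:**
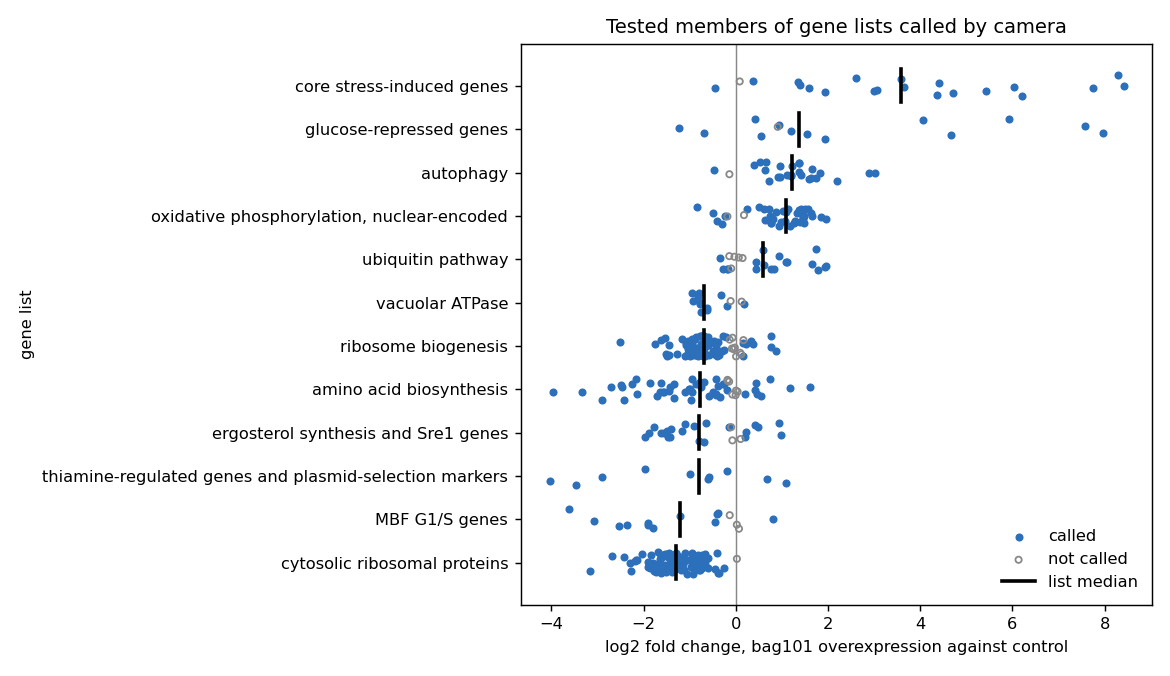
Log2 fold change of bag101 overexpression against control (horizontal axis) for each tested gene of the lists described in the text that camera called with its preset correlation (vertical axis). Filled points are genes called by edgeR, open points are genes not called, and black bars are list medians, from 3.58 for core stress-induced genes to -1.29 for cytosolic ribosomal proteins.

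Biosynthetic genes were lower in several pathways. Of 55 amino acid biosynthesis genes, 40 fell and 8 rose, with a median of -0.77 (camera adjusted p = 2.91e-05, and adjusted p = 0.269 with an estimated correlation). The glutamine synthetase gene gln1 fell 6.58-fold, his1 5.64-fold, arg5 5.41-fold and met9 4.51-fold. Ergosterol synthesis and Sre1 genes were 16 of 25 lower and 6 higher, with a median of -0.80, and erg10, idi1, erg4 and hmg1 fell 3.67-fold, 2.94-fold, 2.82-fold and 2.69-fold. Camera gave this list an adjusted p of 0.0393, adjusted p = 0.509 with an estimated correlation, 0.0557 without overexpression replicate 1 and 0.325 with overlap-free genes only. The list of thiamine-regulated genes and plasmid markers had 8 of 10 lower and 2 higher, with a median of -0.80. The uracil marker gene ura4 fell from 608 ± 21.1 to 37.0 ± 1.93 CPM and the leucine marker gene leu1 from 1510.5 ± 60.4 to 203 ± 22.2 CPM (SD, n = 5 each), while the phosphatase gene pho4 fell 10.98-fold and thi4 3.93-fold. Camera gave an adjusted p of 0.0441 for it, adjusted p = 0.318 with an estimated correlation, 0.0526 without overexpression replicate 1 and 0.154 with overlap-free genes only. The call was lost under 9 settings besides the estimated correlation, among them upper-quartile scaling (0.0769), library totals (0.119), a filter at 10 CPM (0.0523) and protein-coding genes only (0.0521).

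Autophagy genes rose and those of the vacuolar proton pump fell. Of 26 autophagy genes, 24 were higher and 1 lower, with a median of 1.21 (camera adjusted p = 4.05e-06, adjusted p = 0.269 with an estimated correlation and 0.0817 with overlap-free genes only). Atg2402 rose 7.46-fold, the protease gene atg4 4.62-fold, atg1802 3.35-fold and atg17 2.59-fold. In the ubiquitin pathway 14 of 23 genes were higher and 4 lower, with a median of 0.58 (camera adjusted p = 0.0326, adjusted p = 0.575 with an estimated correlation and 0.177 with overlap-free genes only). The ubiquitin-activating enzyme gene uba1 rose from 754 ± 19.6 to 2909 ± 307 CPM (SD, n = 5 each), npl4 3.47-fold, pub3 3.33-fold and ubp15 3.16-fold, while the polyubiquitin gene ubi4 fell by 0.27 ± 0.08 on the log2 scale (SE, adjusted p = 0.00527, edgeR). Levels of ubi4 overlapped between the groups, at 74.1 to 89.7 CPM in controls and 58.7 to 78.6 CPM in overexpression libraries. The proteasome list had 8 of 34 genes higher and 10 lower (camera adjusted p = 0.930), with rpn1301 3.11-fold and rpn6 1.56-fold higher and pre4 1.74-fold lower. Its member pus1, which encodes a pseudouridine synthase, fell 2.62-fold. Of 14 vacuolar ATPase genes, 11 fell and 1 rose, with a median of -0.69 (camera adjusted p = 0.0188, adjusted p = 0.509 with an estimated correlation and 0.523 with overlap-free genes only), and vma4, vma13, vma5 and vma1 fell by 0.94, 0.94, 0.78 and 0.63 on the log2 scale. The median of the overlap-free vacuolar ATPase genes was smaller in size, at -0.31.

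Nutrient uptake lists moved in both directions. Phosphate acquisition genes were 4 of 7 higher and 3 lower. Pho1 and the transporter gene pho84, which fell 10.1-fold, stood against pho842 (2.01-fold higher) and tgp1 (1.68-fold higher). The median was 0.26, the mean -0.96 and camera's direction lower (adjusted p = 0.956). Iron acquisition genes had 5 of 15 higher and 8 lower (camera adjusted p = 0.695), with abc3 3.00-fold lower and isu1, for an iron-sulfur scaffold protein, 2.81-fold higher. The largest falls in this list were outside the naming rule: fip1, frp1 and fio1, of reductive iron uptake, fell 8.07-fold, 7.64-fold and 6.01-fold. Copper and zinc genes were 6 of 9 higher and 2 lower (camera adjusted p = 0.279), with ctr6 3.43-fold higher and the zinc transporter gene zhf1 1.92-fold lower. The nitrogen-limitation list had 8 of 16 higher and 7 lower (camera adjusted p = 0.686), and ptr2, per1, isp6 and psp3 rose 7.34-fold, 6.98-fold, 3.83-fold and 3.54-fold. Outside the naming rule, aat1 fell 8.32-fold and the ammonium transporter gene amt1 2.62-fold.

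Among sexual differentiation genes, 7 of 19 mating genes were higher and 6 lower (camera adjusted p = 0.808), with fus1 2.76-fold higher and map2 2.57-fold lower. Of 14 meiosis genes tested, 6 were higher and 5 lower (camera adjusted p = 0.752), with dli1 5.25-fold and ssm4 2.22-fold higher and rec10 2.48-fold lower. Their median was -0.00 and their mean -0.05, while camera's direction was higher. Spliceosome genes were 17 of 48 higher and 19 lower (camera adjusted p = 0.883), with prp43 2.35-fold lower and cwf16 2.14-fold higher. Their median was 0.00, their mean -0.01 and camera's direction lower. DNA repair genes were 16 of 37 higher and 14 lower (camera adjusted p = 0.686). Rad55 was 3.43-fold, rhp7 3.12-fold, uve1 2.41-fold and the checkpoint kinase gene rad3 2.20-fold higher. Rad17 and the cohesin gene rad21, outside the naming rule, were 3.35-fold and 2.31-fold lower. Rad55, rhp7 and rad3 overlap another counted gene over 61.2%, 47.5% and 66.3% of their length, so their values are uncertain, while uve1 overlaps none. Of 4 tested Tf2 retrotransposons and subtelomeric helicases, 3 fell and none rose (camera adjusted p = 0.215), and Tf2-11 fell from 11.8 ± 0.64 to 2.00 ± 0.64 CPM (SD, n = 5 each). These are near-identical copies, so their counts are uncertain. Camera with its preset correlation called 13 of the 35 lists, 5 higher and 8 lower. With an estimated correlation it called 0, with 5 lists at an unadjusted p below 0.05, whereas fry, which asks only whether the genes of a list move one way on balance, called 31. No called list's median changed sign under RLE, upper-quartile or library-total scaling, and those of 10 of the 22 other lists did.

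The classes of RNA differed in small amounts. Non-coding RNAs took 0.355% ± 0.010 of gene reads in controls and 0.391% ± 0.015 in overexpression libraries (SD, n = 5 each, adjusted p = 0.0111, exact permutation test), and 151 of 351 tested were higher and 100 lower. Small nuclear and nucleolar RNAs rose from 0.0106% to 0.0166%, pseudogenes from 0.0303% to 0.0446% and tRNAs from 0.000696% to 0.00132%, and features missing from the annotation fell from 0.0777% to 0.0570%, each with the same adjusted p in the exact permutation test and with no overlap between groups. Protein-coding genes took 99.52% ± 0.013 and 99.48% ± 0.017 (adjusted p = 0.0278, exact permutation test, n = 5 each), a call lost, at adjusted p = 0.0556, without control replicate 2 or 5 or without overexpression replicate 1, 2, 3 or 5. Ribosomal RNA, at 0.00491% and 0.00462%, did not differ by more than the spread (adjusted p = 0.436, exact permutation test). All class shares leave out reads aligned to more than 1 place, and the library kit is not given. They therefore do not give the amount of ribosomal RNA in the cells.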

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

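The test of the ambiguous reads was chosen only after the result was seen. In 344 sets of 5 values, each a named gene or library measure in 1 of the 2 groups, 30 held a library far from the other 4. Of these, 12 were overexpression 1 and 7 control 2. Chance gives about 1 in 20 for a single set. All sets come from the same 10 libraries and are not independent, so this rate is no test of the 30. Control 2 had 5.54 M gene reads, against 11.3 M to 11.8 M in the other controls, and 5136 genes above 0, against 5270 to 5305.

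In overexpression 1, CPM stood apart for ght3 (1530, others 926 to 1001), smp4 (1503, others 2266 to 2492), inv1 (24443, others 14396 to 17149), rpn1301 (171, others 197 to 202), pht1 (64.1, others 54.8 to 57.0), vma5 (97.6, others 77.1 to 82.7), mam4 (62.1, others 33.95 to 37.01), pus1 (48.3, others 37.7 to 40.2), thi4 (251, others 303 to 313), pol1 (36.2, others 22.1 to 25.1), tos4 (50.9, others 16.58 to 25.95) and pho1 (150, others 69.3 to 84.3). In control 2 it stood apart for hsp78 (164), vma5 (133), prp43 (196), ags1 (735) and adh4 (976). In other controls the separate values were ptr2 (10.6) and met17 (640) in control 1, pub3 (187) in control 3, fus1 (14.7) in control 4 and per1 (44.3) in control 5. In other overexpression libraries they were ker1 (27.1) in replicate 2, his1 (105) and yhb1 (2.87) in replicate 3, and mdj1 (102), tif310 (66.5) and erg10 (122) in replicate 4.

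Reads that the tests did not use also differed between the groups. The ambiguous share of assigned plus ambiguous reads was 21.9% on average in the overexpression libraries, above the 17.0% to 17.3% of the controls. The share of reads in no gene was 0.743%, against 0.392% to 0.435%. In both, all 5 overexpression libraries lay above all 5 controls (p = 0.00794, exact permutation test, the smallest it can give, n = 5 each).

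Bag101 was listed at 0 reads in all 10 libraries. A candidate explanation is that the gene lies inside other counted genes, whose shared reads the counting left unassigned: 89.7% of wholly covered features were at 0 (95% exact interval 87.2 to 91.85), against 7.14% of features without overlap. This fell just short of the 90% set before that share was computed, so the test left the explanation open, while it lay far above the share without overlap (odds ratio 113). The ambiguous share was 4.81 percentage points higher in the overexpression libraries, but that class pools all overlapping genes, so the part of bag101 in it cannot be told apart from theirs. The overexpression that the labels name was not tested by these counts.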

How the results depend on the processing

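The test against a 1.5-fold change, the overlap-free genes, the removal of the 50 most abundant genes and that of 2 libraries together were chosen only after the data were seen. The 3912 calls stayed within 1.5 times under RLE, upper-quartile and library-total scaling, both other filters, DESeq2, limma-voom and protein-coding genes only, from 3472 to 4129. Leaving out each library in turn gave 3859 to 4027 calls, 1864 to 1981 higher and 1992 to 2046 lower, 865 to 890 and 726 to 771 of them over 2-fold, with 11 to 13 lists and 5 to 6 classes. Without control 2 and overexpression 1 there were 3963 calls. With library totals, 1217 genes were lower by over 2-fold, against 730, beside a shift of all genes. With only overlap-free genes, of which fewer were tested, 1907 were called, 947 higher and 960 lower, 435 and 360 of them over 2-fold, and 5 lists. Camera's calls lost there included the MBF (adjusted p = 0.255), vacuolar ATPase (0.523), ubiquitin (0.177), autophagy (0.0817), glucose-repressed (0.0711), ergosterol (0.325) and thiamine lists (0.154). Medians of the overlap-free members were smaller in size for the vacuolar ATPase (-0.31), MBF (-1.04), ergosterol (-0.665) and thiamine lists (-0.55). They were larger for the ubiquitin (0.64), autophagy (1.42) and glucose-repressed lists (3.06). A test against a 1.5-fold change called 2234 genes, 1126 higher and 1108 lower. Camera with an estimated correlation called 0 lists, and fry, which asks only whether the genes of a list move one way on balance, called 31. Among the lists called with the preset correlation, the estimate ran from 0.0398 for thiamine-regulated genes and markers to 0.779 for cytosolic ribosomal proteins. Each of these estimates lay above the preset value, so the adjusted p-values from the preset correlation may be too small. Bag102, not called with TMM factors, became -0.30 and was called lower with library totals. The median of all tested genes moved with it, from -0.03 to -0.39, so this change of sign follows the scaling and is not particular to bag102. No named gene changed its call when 1 library was left out, but most were picked for large changes or a small p. In the test against a 1.5-fold change 13 named genes lost their call, and with library totals 2 did. The list of thiamine-regulated genes and markers lost its call under 9 settings besides the estimated correlation, with adjusted p from 0.0517 to 0.154: upper-quartile factors, library totals, the 10 CPM filter, the replicate block, without overexpression 1, without 2 libraries, protein-coding genes only, overlap-free genes and the 50 most abundant left out. The ergosterol list lost its call under 4, from 0.0515 to 0.325: without overexpression 1, with the replicate block, with protein-coding genes only and with overlap-free genes. For bag101 no alternative gave a value beyond the 0 of its counts, and leaving it out moved nothing.

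Replicate numbers did not pair the samples: correlations of same-numbered samples ran from -0.0882 to 0.0937, none above 0.1, and 2 of 5 controls matched their own number best. With the replicate block 3899 genes were called, 3866 of them also called without it in the same direction, and 11 lists. Depth limits the genes near the floor of 3 reads, such as eno102 and hry1, each with 0 to 2 reads in every control. SPAC186.04c and SPAC3G6.07 also reached 0 reads in a control, so the size of these rises is uncertain. Control 2 was the shallowest library at 5.54 M reads.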

Other observations

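The test without the 50 most abundant genes and that of glucose use or growth arrest were chosen only after the results were seen. Several pairs of related genes changed in opposite directions, and the pairs were chosen after their values were seen, with gpd3, tdh1 and eno101 outside the naming rule. Pyruvate decarboxylase genes changed places: pdc101 fell from 10206 ± 1006 to 887 ± 211 CPM while pdc201 rose from 59.5 ± 3.54 to 10214 ± 1344 CPM (SD, n = 5 each). The glyceraldehyde phosphate dehydrogenase gene gpd3 rose by 2.60 ± 0.37 on the log2 scale (SE, edgeR adjusted p = 9.00e-05) while tdh1 fell by 0.86 ± 0.15 (edgeR adjusted p = 6.01e-05). The enolase gene eno101 fell by 2.68 ± 0.22 (edgeR adjusted p = 3.14e-08), and the Hsp70 genes ssa1 and ssa2 also went opposite ways. The difference within each pair was not tested.

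Large changes lay near chromosome ends more often than elsewhere. Among the tested of the 50 annotated genes nearest each end of the 3 chromosomes in ASM294v3, 27.6% (40 genes, 26 higher and 14 lower) changed more than 8-fold, against 153 of 4514 others (3.39%). The odds ratio was 10.9 (p = 2.10e-23, Fisher's exact test). That test takes genes as independent, while neighbours changed together, so its p-value is too small. Neighbouring tested genes that both changed more than 8-fold in the same direction formed 40 pairs, against a mean of 5.00 and a highest of 14 in 10000 shuffles of the gene order (p = 0.0001, the smallest they can give, permutation test). Families near chromosome ends hold near-identical copies, whose shared reads were not counted.

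Stress and glucose-repressed genes were higher and ribosomal protein genes lower in the overexpression libraries. Of 100 splits of the 10 samples, 1, the real one, gave as many called genes (3912), and the highest of the others gave 0. Every other split mixed libraries of both groups, which widens the spread within each side and keeps its calls low. The splits also count all called genes rather than this pattern. They show that a random division rarely gives so many calls, but cannot tell overexpression from another difference between the groups. A few abundant genes pushing down all others cannot account for the fall of ribosomal protein genes, whose median log2 fold change was -1.48 without the 50 most abundant genes and with libraries scaled to the remaining totals, where the median of all genes was -0.22. That the overexpression cultures had used up their glucose or stopped dividing stays open. Glucose-repressed genes had a median of 1.38 and the G1/S genes of the MBF list fell, which met the prediction. The prediction was set after these values were seen, and the first is part of the pattern itself, so it cannot decide the question. This explanation cannot be told apart from bag101 overexpression because no label gives culture density at harvest. An effect of bag101 itself, which the design names, may be part of the pattern and was not separated from it.

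Ura4 fell far more than the rest of its pathway. Its log2 fold change of -4.04 differed by -2.75 from the median of ura1, ura2, ura3 and ura5, genes outside the naming rule, as controls with more transcribed copies of the marker could give. These other pyrimidine genes had a median of -1.29, with ura2, ura3 and ura5 at -1.10, -1.47 and -1.67 and ura1 at 0.15 (edgeR adjusted p = 0.301), so a fall of the pathway may account for part of the change in ura4. Both explanations met their predictions and stay open. The plasmid marker is not given in the sources used here.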
